A study of Drosophila melanogaster with 6 samples.

How the data were processed

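Gene expression was measured in adult female brains of the CantonS strain on Affymetrix Drosophila arrays, with 3 control arrays and 3 arrays of mushroom body-ablated brains, all per the labels. RNA was extracted with Trizol and labelled with biotin, per the labels' protocols. The deposited table holds 1 intensity per probe set and array on a linear scale, and MAS5 is named in the submitters' processing notes as the tool that made it. Its settings, such as a scaling target, are not given in the sources used here. The analysis was planned on the assumption that these values had been scaled to 1 level per array. The values did not bear this out, since the means of the arrays after trimming 2% at each end were 49.3, 43.3 and 41.3 for control and 40.0, 37.3 and 41.8 for ablated brains. The planned test on unscaled deposited intensities was kept, and its results are given beside 3 scalings.

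Of 14010 probe sets, 44 are Affymetrix control probe sets and were left out before percentiles and tests, a step the written plan did not name. Of the other 13966, 12443 had a single gene in the platform annotation, 327 had several and 1196 had none, and symbols were updated through the gene identifier for 12394. Genes are named from probe sets with a single gene, and a gene with none is unnamed here. Values were taken as log2(intensity + 2.7), where 2.7 is the 20th percentile of all values, so a difference on this scale understates the change of dim genes. The 8381 probe sets whose mean was at or above 9.2, the 40th percentile, were tested, and 7459 of them had a single gene, covering 6865 genes. The highest share of probe sets with identical values on 2 arrays was 1.52%, so no array was counted as a copy of another. Correlations between arrays over tested probe sets averaged 0.948 within control, 0.930 within ablated and 0.938 between the groups. The highest was 0.958, between control 2 and ablated 6, above the highest within control (0.952) and within ablated (0.935). These 2 arrays also had the lowest ratio of 3' to 5' signal of the control probe sets for Gapdh, a sign of RNA integrity and labelling. It was 13.0, 7.18 and 12.7 on control 1, 2 and 3 and 9.37, 10.5 and 7.12 on ablated 4, 5 and 6. The log2 difference between the groups was -0.25 (exact permutation p = 0.5). For actin the ratio was 19.4, 13.0 and 17.3 on control 1, 2 and 3 and 12.5, 17.2 and 14.5 on ablated 4, 5 and 6. The log2 difference for actin was -0.16 (exact permutation p = 0.4), and its lowest ratio was on ablated 4. For arrays, the number of arrays limits the precision.

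Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided) with no covariates, and p-values were adjusted by the Benjamini-Hochberg method at 0.05. Probe sets at least 1.5-fold apart with no overlap between the groups were counted as a description without a variance model. For 30 gene lists written before the data were examined, the brightest tested probe set of each gene was used. The lists cover Kenyon cells, other neurons, glia, signalling, synapses, clock, stress and metabolic families, and tissues that a brain dissection could carry along. They were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, with camera at an estimated correlation and fry as alternatives. Exact permutation tests over arrays were two-sided, and 0.1 is the smallest p they allow here. The first self-test simulated 8381 probe sets with 200 changed by known folds over 5 runs, and 4% of those changed 1.5-fold, 32% of those changed 2-fold, 82.8% of those changed 4-fold and 90.8% of those changed 8-fold were called. In the second, lists of 16 genes lowered by 0.3 on the log2 scale had p under 0.05 in 100% of 100 runs, and unchanged lists in 4%. The simulated genes varied independently, so these shares do not hold for lists whose genes move together. The estimated correlation was 0.35 in the Kenyon cell list and 0.48 in the synaptic list.

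The rule for naming genes was also fixed beforehand. Per direction it names the 12 probe sets with the largest difference among those that pass, or, where fewer pass, the smallest p values up to 6. It also names 6 Kenyon cell genes (ey, dac, rut, dnc, Pka-C1 and Fas2) where measured, and per list the members that pass or, failing that, at most 2 with the smallest p. Genes named outside the rule are said to be so. Alternatives covered the scaling of arrays, the offset, the filter on dim probe sets, the variance model, the list test, the probe set chosen per gene and each array left out in turn. Further alternatives, which left out control 1 and ablated 5 together or asked for a control mean of at least 9.2, were chosen after the data were seen. A list's direction was counted as turned when either camera's direction or the sign of the median changed. This rule was widened, from camera's direction alone, after its first results were seen. The bounds that decide most explanations weighed in the closing section were also set, and changed more than once, after the values were known. For corrections and arrays left out, the bound first concerned the size of the remaining shift and then also asked for array means without overlap, under which no explanation was excluded. In its last form it asks instead that the call stays and that at least 50% of the shift is left, also with each further array left out where 2 arrays or more remain per group. A form that also asked for the call in these further fits would have excluded lower signal that varies with intensity, but not tissue on ablated 5, as the cause of the lower Kenyon cell list. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.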

Results

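RNA from whole brains of adult CantonS females, a wild-type strain of Drosophila melanogaster, was hybridised to 6 Affymetrix arrays. Control brains were measured on 3 arrays (control 1, 2 and 3) and brains without mushroom bodies on 3 arrays (ablated 4, 5 and 6). The mushroom bodies are paired brain centres for olfactory learning, built by intrinsic neurons called Kenyon cells. They were removed with hydroxyurea, an inhibitor of DNA synthesis given here to newly hatched larvae at 25 mg/ml for 4 h, a time at which the mushroom body neuroblasts divide. All flies were kept at 25 °C. The comparison addresses which transcripts are reduced in brains after this ablation. Hydroxyurea is given for every ablated array and for no control array, so other effects of the drug cannot be told apart from the loss of the mushroom bodies. The median signal was 17.6, 14.8 and 14.2 on the control arrays and 14.8, 13 and 14.7 on the ablated arrays, and the number of arrays limits the precision. No label ties the arrays to separate cultures, so p-values measure the spread between these samples, which may be technical.

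Transcripts typical of Kenyon cells were called lower in the ablated brains as a list, by a test at a preset correlation between genes. The Kenyon cell list, fixed before the data were examined, had 16 measured members, and the log2 difference between ablated and control brains lay below 0 for 16 of them. The list had a median difference of -0.36, against a median of -0.17 over all genes, a difference of -0.19 from the other genes (camera, adjusted p = 0.00207 over 30 lists). That call was lost when the correlation between genes was estimated from these arrays, with adjusted p = 0.642 with an estimated correlation. The arrays' list means overlapped, with -0.19 on ablated 6 and -0.21 on control 2 relative to the control mean, the arrays with the lowest 3' to 5' signal ratios of Gapdh (7.12 and 7.18). An exact permutation test gave p = 0.2, where 0.1 is the smallest p that 3 against 3 arrays allow. A split that mixes the groups, control 1, control 3 and ablated 6 against the rest, gave a larger shift from all genes, 0.31 in size. Its unadjusted camera p was 4.67e-05, against 0.000276 for the real split. The synaptic list described below stood at -0.23 from all genes, and the Kenyon cell mean less the synaptic mean overlapped between the groups (exact permutation p = 0.6). With control 1 and ablated 5 both left out, an alternative added after the data were seen, the median was -0.21 and camera's adjusted p was 0.0799. These arrays had the highest and lowest list means, so leaving them out narrows the gap between the groups by construction.

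The gene eyeless (ey, probe set 143543_at), a Pax6 transcription factor needed for mushroom body development, had the smallest p of all lower probe sets. Its signal was 220 ± 41.9 (SD, n = 3) in control brains and 109 ± 11.0 (SD, n = 3) in ablated brains, a log2 difference of -0.99 (SE 0.18), with every ablated array below every control array. Its adjusted p over all probe sets was 0.554. Of the 16 Kenyon cell genes, 0 passed limma's test over all probe sets and 3 passed when adjusted over the list alone. These were ey, with adjusted p = 0.00475, prt (143798_at), which encodes the vesicular transporter portabella, with 0.0306, and toy (152583_at), the second Pax6 gene, with 0.0450. Adjustment over the list alone does not cover the 30 lists. It also rests on deposited values tested against no difference, where the median of all genes was -0.17. A lower overall signal of the ablated arrays therefore enters these p-values. The signal of prt was 24.2 ± 2.26 (SD, n = 3) in control and 8.40 ± 5.55 (SD, n = 3) in ablated brains, and that of toy was 448 ± 56.9 (SD, n = 3) and 302 ± 55.1 (SD, n = 3). The genes prt and toy were named after their values were seen.

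**Figure D1:**
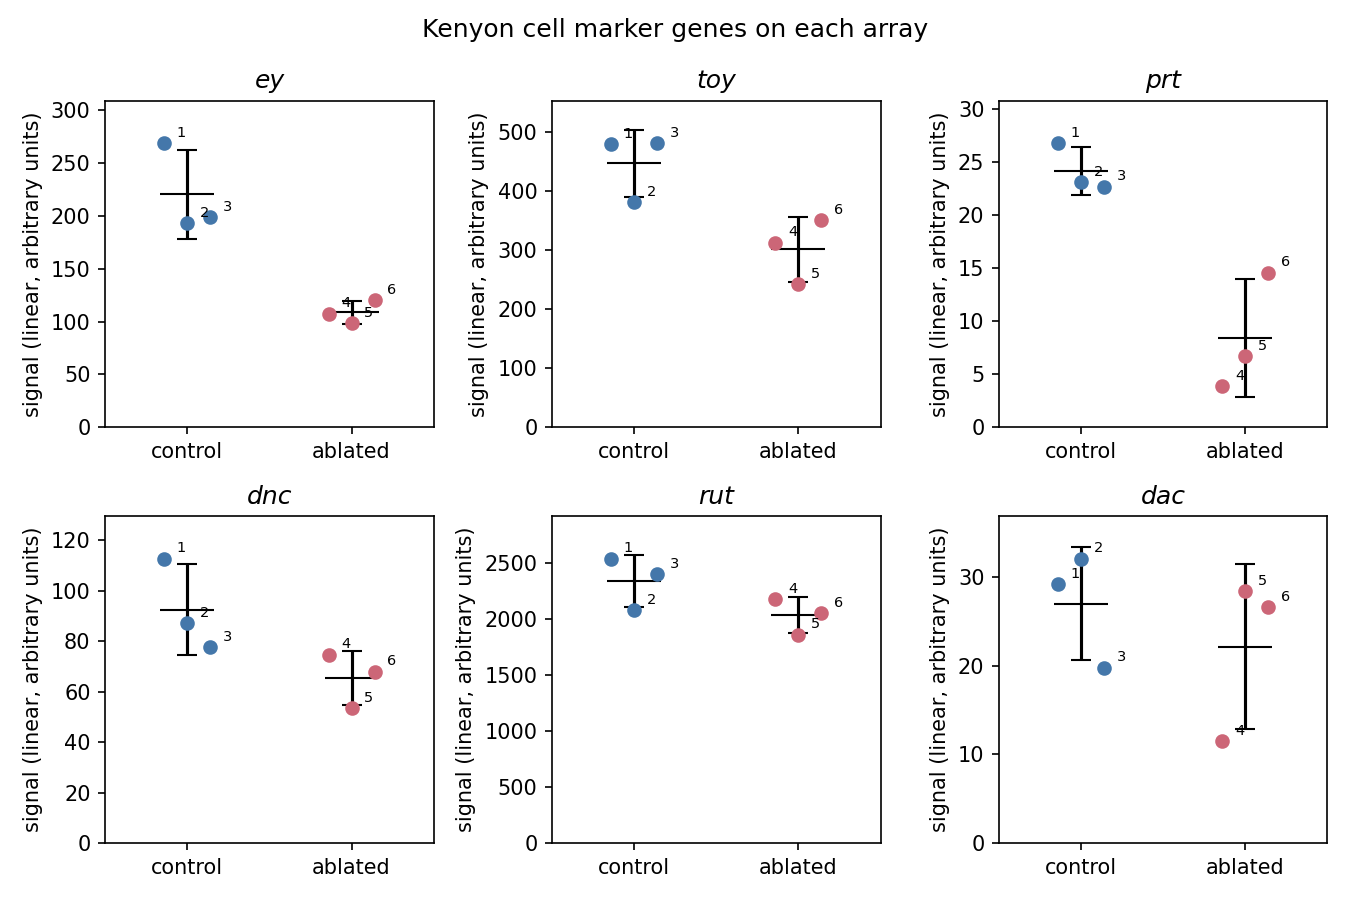
Signal of 6 Kenyon cell marker genes on a linear scale starting at 0, in arbitrary units, with each numbered point being 1 array and the bars the mean and SD of 3 arrays. The ablated arrays lie below the control arrays for ey, toy, prt and dnc, and the groups overlap for rut and dac. Each gene is shown by its brightest tested probe set, which for rut is 151241_f_at.

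Among the other Kenyon cell genes fixed for naming, dunce (dnc, 152476_at), the cAMP phosphodiesterase of olfactory learning, had a log2 difference of -0.48 (SE 0.20). It measured 92.6 ± 18.1 (SD, n = 3) in control and 65.4 ± 10.8 (SD, n = 3) in ablated brains, and dimmer probe sets (143128_at and 144435_at) stood at -0.19 and 0.24. The brightest probe set of rutabaga (rut, 151241_f_at), the calcium-responsive adenylyl cyclase, differed by -0.20 (SE 0.11) with overlapping groups, and a dimmer one (143329_at) by -0.77 (SE 0.28). The values for dachshund (dac, 143574_at) differed by -0.32 (SE 0.33), and by 0.046 without ablated 4. Pka-C1 and Fas2 had no probe set named with a single gene here.

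Over all probe sets, limma called 0 lower and 0 higher in ablated brains among 8381 tested, with 0.554 the lowest adjusted p. At an unadjusted p under 0.05 there were 661 lower and 53 higher probe sets in the deposited values, where chance gives 210 per direction. These counts moved with the scaling of the arrays. They were 333 lower and 146 higher with median-centred arrays, 224 and 192 after quantile normalization and 176 and 222 after cyclic loess. Without a variance model, 268 probe sets were at least 1.5-fold lower and 40 at least 1.5-fold higher with no overlap between the groups. At any fold, 14.8% of the tested probe sets had every ablated array below every control array and 1.26% had every ablated array above, where chance gives 5% per direction and 10% in all. For probe sets 1.5-fold apart, splits that mix the groups ranged from 230 lower and 36 higher (control 1, control 2 and ablated 6 against the rest) to 61 and 61 (control 1, control 3 and ablated 5). Without control 1 and ablated 5, the arrays with the highest and lowest median signal, the excess turned, with 213 lower and 269 higher. Lower counts with 1 array left out were 257, 505 and 527 without control 1, 2 and 3 and 539, 223 and 698 without ablated 4, 5 and 6. Higher counts were 190, 134 and 62 without control 1, 2 and 3 and 88, 86 and 115 without ablated 4, 5 and 6, where fewer arrays make overlap rarer. The imbalance also moved with the scaling of the arrays. The lower share of the probe sets 1.5-fold apart was 87.0% for the deposited values, 64% with median-centred arrays (128 lower, 72 higher), 58.8% after quantile normalization (117 and 82) and 50% after cyclic loess (95 and 95). The median difference of the tested probe sets was -0.17, -0.064, -0.024 and 0.0028 in these 4 cases. Under all 4 scalings, 91 probe sets of 79 genes were lower and 39 probe sets of 33 genes were higher. These 130 are no more than splits that mix the groups can give. Of the 10 splits of the arrays, 5, the real split among them, gave as many, and the highest gave 226. Simulated arrays of the same size gave a call for 32% of probe sets changed 2-fold and 82.8% of those changed 4-fold.

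After ey, the lower probe sets with the smallest p belonged to CG17221 (145688_at), CG12253 (154625_at), Ctf4 (141540_at), which encodes a replication fork protein, pHCl-1 (148832_at), a pH-gated chloride channel, and CG14483 (147379_at). Their adjusted p was 0.554 and their groups did not overlap. The signal of Ctf4 was 19.7 ± 3.16 (SD, n = 3) in control and 4.67 ± 1.36 (SD, n = 3) in ablated brains, and that of pHCl-1 was 23.6 ± 1.91 (SD, n = 3) and 8.37 ± 2.06 (SD, n = 3). A brighter probe set of pHCl-1 (148831_at) differed by only -0.16, from 75.7 to 68.1. CG17221, CG12253 and CG14483 had log2 differences of -0.90, -0.87 and -0.76.

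On the higher side, the smallest p values among probe sets with a single gene belonged to CG17224 (145684_at), wat (150796_at), a fatty acyl-CoA reductase of the tracheal system, pio (152422_at), a zona pellucida domain protein of the apical extracellular matrix, CG6891 (141412_at), Obp56d (147516_at) and Cyp4aa1 (147268_at). All 6 had an adjusted p of 0.554 and no overlap between the groups, and a second probe set of CG6891 stood at 0.48. CG17224 measured 19.1 ± 3.65 (SD, n = 3) in control and 53.5 ± 16.2 (SD, n = 3) in ablated brains. The values for wat were 95.8 ± 56.2 (SD, n = 3) and 308 ± 115 (SD, n = 3), and those for pio were 11.1 ± 5.10 (SD, n = 3) and 36.4 ± 14.5 (SD, n = 3).

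Genes of the synaptic vesicle and active zone, present in neurons of many kinds, were the other list called lower. Of 13 measured members, 12 lay below 0, with a median of -0.40, which is -0.23 from that of all genes (camera, adjusted p = 0.0294, and adjusted p = 0.852 with an estimated correlation). The call was lost without control 1 (median -0.21, adjusted p = 0.301), without ablated 5 (-0.27, adjusted p = 0.107) and without ablated 6 (-0.42, adjusted p = 0.226). Of its members, 0 passed over all probe sets and 1 passed when adjusted over the list alone. That was Csp (141486_at), a synaptic vesicle chaperone, at 399 ± 35.5 (SD, n = 3) in control and 270.2 ± 32.2 (SD, n = 3) in ablated brains (adjusted p = 0.0480 over the list alone). That p-value is not adjusted over the 30 lists and tests against no difference, not against the other genes. Rim (150106_at), an active zone scaffold, differed by -0.47 (SE 0.18), while its 2 other tested probe sets (150107_at and 150109_at) stood at -0.13 and 0.10.

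Odorant-binding proteins, carriers of odorants secreted mostly in the antennae and taste organs, were called higher as a list. Their list means overlapped, with 0.32 on control 1 and 0.30 on ablated 4 (exact permutation p = 0.2). Of 12 measured members, 10 lay above 0, with a median of 1.11 and a difference of 1.28 from that of all genes (camera, adjusted p = 1.92e-07, and adjusted p = 0.512 with an estimated correlation). Of the 12, 8 had a control mean of at least 9.2, the level for testing, and the other 4, among them Os-C, Obp28a and Obp83b, were tested only because of their ablated arrays. An alternative added after the data were seen asked that level of the control mean. It leaves out genes rising from low signal and admits probe sets whose mean over all arrays lies below 9.2. The median over the 9 members then tested was 0.11 and the difference from all genes 0.29 (camera, adjusted p = 0.00237). In the list of 12, 0 passed when adjusted over all probe sets and 0 when adjusted over the list alone. Much of the list's shift came from ablated 5, and without it the median was 0.23 (adjusted p = 0.00531). On that array Os-C read 237, Obp28a 119 and Obp83b 218, against at most 1.30, 3.50 and 11.7 on the control arrays. On ablated 6 these 3 genes read 16.3, 19.2 and 13.7, and on ablated 4 they read 0.90, 1.80 and 4.10. Obp56d and Obp19d (153423_at) were higher on each ablated array than on each control array, with log2 differences of 1.88 (SE 0.55) and 1.97 (SE 0.65). Os-C, Obp28a and Obp83b were named after their values were seen.

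**Figure D2:**
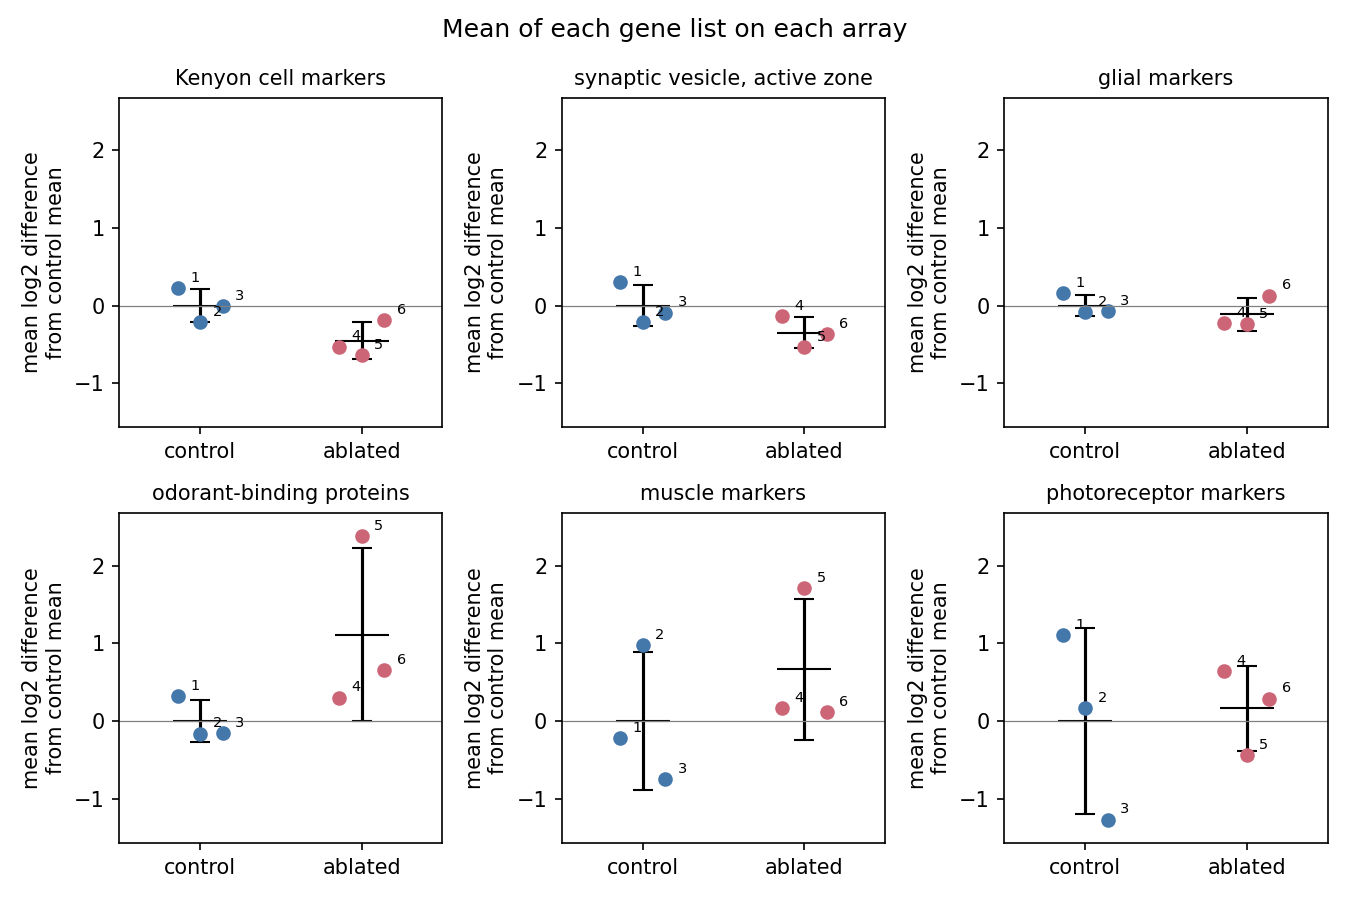
Mean over the members of 6 gene lists on each array, as the log2 difference from the mean of the control arrays, with each numbered point being 1 array and the bars the mean and SD of 3 arrays. Ablated 5 stands at 2.38 for odorant-binding proteins and 1.72 for muscle markers, and the Kenyon cell list lies lowest on ablated 4 and ablated 5.

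Muscle markers were called higher as a list, with 8 of 9 members above 0 and a median of 0.75, which is 0.93 from that of all genes (camera, adjusted p = 0.000136, and adjusted p = 0.642 with an estimated correlation). The arrays' list means overlapped, with 0.97 on control 2 against 0.17 on ablated 4 and 0.11 on ablated 6 (exact permutation p = 0.4). Camera's call of the muscle list was lost without ablated 5 (median 0.18, adjusted p = 0.131). The myosin light chain gene Mlc2 (143265_at) read 779 on ablated 5, 450 on control 2 and between 51.4 and 159 on the other arrays. Cytochrome P450 genes, which encode oxidases of hormones and foreign compounds, had a median of 0.037 over 48 members, which is 0.21 from that of all genes (adjusted p = 0.000136, and adjusted p = 0.642 with an estimated correlation). Without ablated 5 their median was -0.056 (adjusted p = 0.249). Within the family Cyp4aa1 differed by 0.93 (SE 0.28) and Cyp4s3 (145104_at) by -1.08 (SE 0.37). Antimicrobial and immune genes were called higher as a list of 7, with a median of 0.32, which is 0.49 from that of all genes (camera, adjusted p = 0.00565, and adjusted p = 0.512 with an estimated correlation). Their list means overlapped, with 0.33 on control 3 against 0.17 on ablated 5 and 0.19 on ablated 6. Their call was lost without control 1 (0.058, adjusted p = 0.129), control 2 (0.21, adjusted p = 0.0771) or ablated 4 (0.27, adjusted p = 0.10). The antifungal peptide gene Drs (143605_at) differed by 0.55 (SE 0.32) and BomS2 (144068_at) by 0.63 (SE 0.38). In these 3 lists 0 genes passed over all probe sets and 0 when adjusted over the list alone.

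With an estimated correlation, 0 of the 6 called lists kept an adjusted call in camera. At an unadjusted p under 0.05 there were 2, odorant-binding proteins and antimicrobial genes, and limma's fry, a test of movement in a single direction, gave 0 after adjustment.

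None of the other 24 lists passed the adjusted test. Learning and memory genes had a median of -0.32 over 16 members (adjusted p = 0.0515) and ion channels -0.36 over 18 (adjusted p = 0.0515). The list of ion channels included the potassium channel genes sei (152427_at), at -0.41 (SE 0.13), and Elk (151507_at), at -0.78 (SE 0.26), with a second Elk probe set at -0.25. Among learning genes 14-3-3zeta (153924_at) differed by -0.40 (SE 0.17). The adjusted p of learning genes fell below 0.05 under median centring (0.0384), quantile normalization (0.0428) and cyclic loess (0.0402), without control 2 (0.00502) or ablated 4 (0.0213), and with the level for testing asked of the control mean (0.0434). That of ion channels did so under median centring (0.0384), with no filter (0.0358) and without control 2 (0.000538). Projection neuron markers had a median of -0.31 over 7 members (adjusted p = 0.786). Of these, Lim1 (144141_at), a LIM-homeodomain transcription factor gene, measured 31.6 ± 5.60 (SD, n = 3) in control and 12.7 ± 8.27 (SD, n = 3) in ablated brains and passed when adjusted over the list alone (adjusted p = 0.0445). That p-value, too, is not adjusted over the 30 lists and tests against no difference. The medians of the transmitter lists were -0.25 for cholinergic, -0.21 for GABA, -0.23 for glutamate, -0.043 for monoamine and -0.15 for neuropeptide genes. Members with the smallest p in the first 3 of these lists were nAChRalpha2 (152882_at) at -0.51 and nAChRbeta1 (152309_at) at -0.57, Lcch3 (152194_at) and VGAT (147191_at) both at -0.49, and Eaat2 (152272_at) at -0.38 and Nmdar1 (143612_at) at -0.46. In the other 2 they went both ways, with Ddc (152611_at) at -0.20 and Vmat (152678_at) at 0.17 (-0.081 without control 2), and ITP (141624_at) at -0.59 and Nplp4 (151194_r_at) at 0.44, the last higher on each ablated array than on each control array. Signalling genes of the cAMP and calcium pathways had a median of -0.20, with the G protein gene Galphao (142441_at) at -0.82 (SE 0.22) and Pkc98E (151525_at) at -0.45 (SE 0.14), while a second probe set of Pkc98E stood at -0.027. Receptors for amines and acetylcholine had -0.23, with 5-HT1B (143484_at) at -1.06 (SE 0.42) and Octbeta3R (149783_at) at 0.70 (SE 0.42), and adhesion and axon guidance genes had -0.19, with fra (143665_at) at -0.69 (SE 0.22) and Sema1a (143641_at) at -0.73 (SE 0.27).

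Glial markers had a median of -0.15 over 14 members (adjusted p = 0.786), and 0 of them separated the groups. Photoreceptor markers had a median of 0.25 (adjusted p = 0.119) and fat body and yolk genes 0.085 (adjusted p = 0.0515). Arr2, a photoreceptor arrestin, read 1085, 409 and 42.7 on control 1, 2 and 3, and the fat body genes fit and Lsp2 read 1060 and 1414 on control 1 and at most 402 and 687 on the other arrays. Without control 1, photoreceptor markers (0.90, adjusted p = 0.00702) and fat body genes (0.36, adjusted p = 7.98e-08) passed the test, and fat body genes also did without ablated 6 (0.16, adjusted p = 0.0286). With array weights their adjusted p was 0.0172 and 0.00658, and that of fat body genes was 0.0365 with the level for testing asked of the control mean. Arr2, fit and Lsp2 were named after their values were seen. Medians of the remaining lists were -0.18 for haemocyte markers, -0.16 for DNA replication and damage genes, -0.14 for heat shock genes, -0.37 for clock genes, 0.054 for digestive enzymes and -0.064 for ribosomal proteins. They were 0.0026 for odorant and gustatory receptors, -0.21 for Jonah proteases, -0.0091 for glutathione S-transferases and -0.16 for reference genes, with adjusted p between 0.0515 and 0.979 over these 10 lists. Glutathione S-transferases passed, on the higher side, under median centring (adjusted p = 0.0414), quantile normalization (0.0419), cyclic loess (0.0402), without control 2 (0.0355) or ablated 6 (0.0073), and with the level for testing asked of the control mean (0.0434). On the same side were ribosomal proteins under cyclic loess (0.0419) and chemoreceptors with no filter (0.00909). In 8 lists camera placed the members above the other genes although their median lay below 0, and all genes had a median of -0.17. These were amine receptors, monoamine, neuropeptide, glial, haemocyte, DNA replication, ribosomal and glutathione S-transferase genes, and the mean of the last list was 0.0029.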

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

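The rule that picked out the next 3 probe sets, the tests on list means and medians per array, the division by the spikes, the fits with a further array left out, and the bounds set on the planned fits after cyclic loess or without an array were chosen after the results were seen. Among 5585 probe sets too dim on average to be tested, 3 had a signal of at least 20 on an ablated array and at least 10 times that of the highest control array, and 0 met the mirror rule with a control array on top. The gene lush (143917_at), an odorant-binding protein of pheromone-sensing antennal hairs, read 46.8 on ablated 5 against at most 1.20 on the control arrays, and 5.60 on ablated 6. CG9747 (152137_at) read 38.1 on ablated 4, at most 1.80 on the control arrays and 0.70 on both other ablated arrays. CG7409 (148360_at) read 23 on ablated 5 and at most 1.20 on the control arrays. Of the 12 measured odorant-binding proteins, 8 had a control mean of at least 9.2, the level for testing, which is a percentile of all signals and shows no detection. The other 4 include Os-C, Obp28a and Obp83b, which had the largest log2 differences of the list, and 0 of the 12 are in another list.

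The higher signal of odorant-binding proteins may come from antennal tissue left on some brains or from a difference between the groups. Antennal tissue on ablated 5 alone would leave no shift without that array, and the list then kept 27.3% of its shift, 0.35 above all genes (camera, adjusted p = 0.00531), but in the 3 fits with a control array also left out it kept as little as 11.3%, with the call held in 3, so whether ablated 5 is the whole cause stays open. These calls use the preset correlation, and with an estimated correlation the call on all 6 arrays was lost (camera, adjusted p = 0.512). A difference present on every array would separate the groups, and the lowest ablated list mean lay -0.016 from the highest control mean, within the control arrays' spread. Antennal tissue on ablated 5 and ablated 6 would leave ablated 4 at the control level. The median over the list on ablated 4 stood 0.17 above the control mean, close to control 1 at 0.14, with control 2 and 3 at -0.063 and -0.11. Ablated 4 was thus near the control level, as that explanation asks. Ablated 5 stood at 2.61, but ablated 6 only at 0.24, so the medians do not separate the explanations. Of the 10 splits of the 6 arrays, which are too few for a share under 0.05, only 1, the real split itself, gave a camera p as small as 6.4e-09. The smallest of the other splits was 8.53e-07.

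The lower Kenyon cell list is the change that the ablation would give, but its adjusted p ran from 0.000107 to 0.642 over the alternatives and was 0.0799 without control 1 and ablated 5. These arrays had the highest and lowest list means (0.22 and -0.64), so leaving them out narrows the gap between the groups by construction. The shift is measured from all genes, so a uniformly lower signal of the ablated arrays was already subtracted. It stood at -0.187 both as deposited and with median-centred arrays. Cyclic loess could therefore only test lower signal that varies with intensity, which as the whole cause would end the shift. The values argue against that form, since the list then stood at -0.196 from all genes (camera, adjusted p = 0.000637). With 1 array also left out it stood at -0.28 to -0.17, with the call kept in 6 of 6 fits. A bound asking for no overlap of the array means would have left this and the next explanation open. Other tissue on ablated 5 as the whole cause would end the shift without that array. The size of the shift argues against it, since 96.9% was left, at -0.181 (camera, adjusted p = 0.0177). At least 81.7% was left in the 3 fits with a control array also left out. Of these, the call was lost without control 1 (-0.15, adjusted p = 0.0799), so a bound asking for the call there would have left this explanation open. The calls on this list use the preset correlation, and with an estimated correlation the call on all 6 arrays was lost (camera, adjusted p = 0.642). Fewer neurons of every kind would lower synaptic genes alike, and the Kenyon cell mean less the synaptic mean differed by -0.10 between the groups (exact permutation p = 0.6), which leaves it open. Of the 10 splits, too few for a share under 0.05, 2, the real split among them, gave a camera p of 0.000276 or less. The smallest of the other splits was 4.67e-05, for control 1, control 3 and ablated 6 against the rest.

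The excess of lower over higher probe sets may reflect array brightness. After division by the hybridisation spikes, the log2 difference of the array medians was -0.066, from -0.13 before, with overlapping arrays (exact permutation p = 0.6). Without the bright array control 1 the median difference of tested probe sets was -0.11, from -0.17 with it. Without control 1 and ablated 5 the excess turned, with 213 lower and 269 higher. These arrays have the highest and lowest median signal, so leaving them out narrows the brightness gap by construction. Splits that mix the groups could also give more lower probe sets in the group without control 1. At 1.5-fold with no overlap there were 230 lower and 36 higher for control 1, control 2 and ablated 6 against the rest, but 61 and 61 for control 1, control 3 and ablated 5. Both brightness explanations therefore stay open beside a loss of transcripts in the ablated brains.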

How the results depend on the processing

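The alternatives without control 1 and ablated 5 and with the filter on the control mean, and the genes named outside the rule, were chosen after the data were seen. No paired analysis was possible because the control and ablated arrays share no replicate numbers. Limma called 0 probe sets in either direction under every alternative that keeps the threshold on adjusted p, including 0.1. At an unadjusted p under 0.01 there were 80 lower and 9 higher in the deposited values, where chance gives 42 per direction. There were 47 and 19 with median-centred arrays, 30 and 30 after quantile normalization and 22 and 35 after cyclic loess. Low signal limits the dim probe sets, whose log2 differences depend most on the offset and the filter. A robust trend was not run for the lists, since camera has no such option. The cause of the changes below was not tested, except where fewer arrays or probe sets enter by construction.

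Probe sets at least 1.5-fold apart with no overlap, 268 lower and 40 higher with the chosen settings, numbered 128 and 72 with median-centred arrays, 117 and 82 after quantile normalization and 95 and 95 after cyclic loess. They numbered 120 and 25 with the offset at the 40th percentile, 451 and 150 with no filter, 141 and 9 with the filter at the 60th percentile, 326 and 21 with the filter on the control mean and 27 and 17 at 2-fold. Leaving out each array in turn gave 223 (without ablated 5) to 698 (without ablated 6) lower and 62 (without control 3) to 190 (without control 1) higher, where fewer arrays make overlap rarer. Without control 1 and ablated 5 the excess turned, with 213 lower and 269 higher.

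The Kenyon cell list kept its direction under every alternative, and its call under all except 3. The median was -0.36 with camera's estimated correlation (adjusted p = 0.642) and -0.36 with fry (adjusted p = 0.466), and -0.21 without control 1 and ablated 5 (adjusted p = 0.0799). Leaving out each array gave medians of -0.51 to -0.29. Of the other lists, 5 passed with the chosen settings, 8 with median-centred arrays, 8 after cyclic loess, 8 with the filter on the control mean, 0 with an estimated correlation, 0 with fry, 3 without control 1 and ablated 5, and 2 (without ablated 5) to 7 (without control 2) when an array was left out.

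Of 81 named probe sets, 73 kept their sign under every alternative that tested them. The others ranged with 1 array left out from -0.52 to 0.046 for dac, -0.081 to 0.38 for Vmat, -0.88 to 0.043 for trpl, -0.47 to 1.82 for Arr2, -0.14 to 1.49 for Lsp2 and -0.42 to 1.48 for fit. Without control 1 and ablated 5, trpl stood at 0.37, Mlc2 at -0.065 and betaTub56D at 0.056.

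Across the other 29 lists and their alternatives, 458 values were the same, 25 lost a call, 18 gained one and 107 turned in camera's direction or in sign, 9 of them with fry, which tests against 0 and not against other genes. Apart from muscle without control 1 and ablated 5 and cytochrome P450 with an array left out, the lists that turned were not called with the chosen settings. The medians in those cases were as follows. With median-centred arrays they were -0.13 for amine receptors, 0.067 for monoamine genes, -0.048 for DNA replication, 0.046 for ribosomal proteins, 0.10 for glutathione S-transferases and -0.047 for reference genes. Quantile normalization gave -0.096 for amine receptors, 0.13 for monoamine genes, 0.019 for neuropeptides, 0.0098 for glia, 0.0045 for haemocytes, -0.010 for DNA replication, 0.010 for heat shock, 0.048 for ribosomal proteins, 0.17 for glutathione S-transferases and -0.043 for reference genes. Cyclic loess gave -0.064 for amine receptors, 0.15 for monoamine genes, 0.049 for neuropeptides, -0.013 for axon guidance, 0.048 for glia, 0.023 for haemocytes, 0.016 for DNA replication, 0.039 for heat shock, 0.089 for ribosomal proteins, 0.20 for glutathione S-transferases and -0.00030 for reference genes. With no filter they were -0.25 for amine receptors, -0.16 for glia, -0.18 for haemocytes, 0.052 for DNA replication, -0.013 for chemoreceptors and 0.034 for Jonah proteases. The filter at the 60th percentile gave -0.031 for projection neurons, -0.19 for axon guidance, -0.29 for DNA replication, -0.13 for heat shock, -0.071 for chemoreceptors and -0.16 for reference genes. The filter on the control mean gave -0.19 for axon guidance, -0.25 for DNA replication, -0.088 for digestive enzymes, -0.37 for chemoreceptors, -0.17 for Jonah proteases and -0.16 for reference genes. The floor gave -0.0018 for chemoreceptors, the fit without trend -0.18 for haemocytes, and array weights -0.20 for cAMP and calcium signalling, -0.19 for axon guidance and -0.18 for haemocytes. With fry they were -0.23 for amine receptors, -0.043 for monoamine genes, -0.15 for neuropeptides, -0.15 for glia, -0.18 for haemocytes, -0.16 for DNA replication, -0.064 for ribosomal proteins, 0.0026 for chemoreceptors and -0.0091 for glutathione S-transferases. Without control 1 and ablated 5 they were -0.020 for cAMP and calcium signalling, 0.12 for amine receptors, -0.061 for cholinergic genes, 0.056 for monoamine genes, 0.021 for neuropeptides, -0.011 for axon guidance, 0.075 for glia, -0.15 for haemocytes, -0.018 for muscle, -0.043 for ribosomal proteins, -0.26 for chemoreceptors, -0.097 for Jonah proteases, 0.0087 for glutathione S-transferases and 0.034 for reference genes. With 1 array left out the medians ranged from -0.28 to -0.055 for cAMP and calcium signalling, -0.36 to -0.053 for amine receptors, -0.12 to 0.038 for monoamine genes, -0.31 to -0.031 for axon guidance and -0.22 to -0.011 for glia. They ranged from -0.47 to 0.90 for photoreceptors, -0.14 to 0.36 for fat body, -0.28 to -0.092 for haemocytes, -0.28 to -0.11 for DNA replication and -0.33 to -0.029 for heat shock. For the remaining lists they ranged from -0.099 to 0.28 for digestive enzymes, -0.12 to -0.034 for ribosomal proteins, -0.15 to 0.18 for chemoreceptors, -0.29 to -0.074 for Jonah proteases, -0.056 to 0.097 for cytochrome P450, -0.12 to 0.047 for glutathione S-transferases and -0.20 to -0.045 for reference genes.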

Other observations

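The test over lists of clock genes was planned, and the choice to describe these genes, including vri, cyc and per, was made after their values were seen. Of 8 genes of the circadian clock, 5 had every ablated array below every control array and 1 had the reverse. The transcriptional repressor genes cwo (151642_at) and tim (142154_at) had log2 differences of -0.61 (SE 0.22) and -0.54 (SE 0.21), vri -0.46 (SE 0.18) and cyc -0.37 (SE 0.16), while per stood at 0.40 (SE 0.23). The list means did not overlap between the groups (difference -0.27, exact permutation p = 0.1, the smallest that 3 against 3 arrays allow). With median-centred arrays the difference was -0.16, and the highest ablated mean (-0.085) lay just below the lowest control mean (-0.079). The list did not pass fry (adjusted p = 0.170) or camera (adjusted p = 0.172), and 0 of its genes passed when adjusted over the list alone.

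Counts over all 10 splits of the 6 arrays, too few for a share under 0.05, were as follows. Each number of splits that reached the real count includes the real split. The real split gave 0 probe sets past limma's adjusted threshold, as did all 10, and the highest other count was 0. At an unadjusted p under 0.01 in limma the real split gave 89, and the highest counts in splits that mix the groups were 107 and 106. For probe sets at least 1.5-fold apart with no overlap, the real split gave 308, the highest other 289, and 1 split reached the real count. After cyclic loess the real count was 190 and the highest other 313, with 4 splits at or above the real one. Under all 4 scalings it was 130 against 226, with 5 splits. The real split put 6 lists past camera's adjusted threshold, the highest other put 8, and 3 splits put as many as the real one.

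After the data were seen, Fisher's exact test was used to ask which lists held more of the 31 genes at least 1.5-fold higher with no overlap than the 6865 tested genes did. Odorant-binding proteins held 3 of these genes among 12 (25% against 0.452%, adjusted p = 0.000535), and 2 of 16 Kenyon cell genes were among the 213 lower genes (12.5% against 3.10%, adjusted p = 1). The odorant-binding proteins had already been called higher on the same arrays, and Fisher's test treats genes as independent, so it adds no separate evidence. Their estimated correlation was 0.25, with which camera gave adjusted p = 0.512.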
